A study of Gossypium with 24 samples.

How the data were processed

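RNA sequencing libraries of cotton seedling roots were compared in 24 libraries, 3 for each of 8 groups. The groups cross 2 varieties, named 9001 and 4847, with 2 treatments and 2 sampling times. Each library was assigned to its group from its own label. Per the labels' protocols, RNA was extracted with a Qiagen RNeasy mini plus kit and libraries were made with a SMARTer mRNA-Seq kit from total RNA. Nothing in the labels says whether the 3 libraries of a group came from separate plants, so p-values measure only the spread between these libraries, which may be technical.

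The deposited count table holds whole-number counts per gene ID for 60633 IDs, with no normalization, and was used as deposited. The deposited FPKM table lists the same IDs. For 60632 of them each FPKM above 0 equalled the count per column total and per gene length within a relative difference of 1e-06, with a length that was whole within 0.01 bases, so that FPKM is scaled by library totals alone. The 1 remaining FPKM line was malformed and was left out of the FPKM alternatives. The aligner, the counting tool, the use of strand and the treatment of reads that match several places are not given in the sources used here. Per the submitters' processing notes the genome build is mm10, a mouse assembly, whereas all IDs carry an A or D chromosome label (29793 A and 30840 D, on 26 chromosomes), so the build behind the counts is not known. Cotton carries A and D copies of many genes, and counts of near-identical copies are uncertain where reads could match both.

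The files do not pair the IDs with gene names or descriptions, and no annotation was used here. Pathway and cell type lists fixed before the data were examined were defined by gene descriptions, so none of them could be applied. They included the GABA shunt, fermentation, glycolysis and respiration lists that match the study's title. The set tests planned for them, camera and fry, were not run. The rule for named genes therefore fell back on IDs. Named here are the 2 IDs with the largest fitted rise and the 2 with the largest fitted fall under waterlogging at 0 h in 9001, among genes with adjusted p under 0.05, a mean of at least 5 CPM in the higher group and no overlap between the libraries of the groups. The same 4 IDs are followed through the other comparisons.

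Counts were tested with edgeR 4.0.16 (filterByExpr, TMM scaling, estimateDisp, glmQLFit and glmQLFTest) in R 4.3.3. All 24 libraries entered 1 fit with a coefficient per group and 16 residual degrees of freedom. The fit shares 1 estimate of the spread per gene over all groups. Where groups differ in spread, p-values may be too small for the more variable group and too large for the less variable. After filtering, 50638 genes were tested in 13 contrasts, each with Benjamini-Hochberg adjustment and a threshold of 0.05. The number of genes that also changed at least 2-fold is given beside each count. An SE given with a log2 fold change is the size of that change divided by the square root of the F statistic of its test. It is approximate and unreliable where a group has few counts. CPM values are scaled with the TMM factors, whose group means ran from 0.584 in waterlogged 9001 at 0 h to 1.47 in the 24 h controls. A fold against a group with no counts was computed against a floor of 3 counts over the group and is a lower bound, and ratios of low counts carry exact 95% intervals that cover counting error only. Differences in a single measure per library were tested with exact two-sided permutation tests (scipy 1.17.1), which for 3 against 3 libraries cannot give a p below 0.1.

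Each library was placed on 2 axes taken from the other variety, so that no library defined its own axis. The control axis was the difference between the control groups at 24 h and 0 h, and the waterlogging axis the difference between waterlogged and control groups at 0 h, both in mean log2 CPM over the tested genes. Coordinates are the coefficients of a regression through the origin on both axes. The varieties were compared with each other on axes averaged over both. Groups of genes that rose or fell from 0 h to 24 h were likewise selected in the other variety's controls. No control was kept dark for the further 24 h, so re-lighting and elapsed time are not separated on this axis or in these groups.

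Totals ran from 21423479 to 39945111 counts per library. In simulated data drawn from the libraries' own means and sizes, the test recovered 42% of genes changed 1.5-fold and 86% of those changed 3-fold in the comparison of waterlogging at 0 h in 9001, with 4 false calls among 49774 unchanged genes. The recovered shares were 62% and 92% for waterlogging at 24 h in 4847, with 6 false calls among 49993 genes, and 37% and 81% for the difference between varieties at 24 h, with 9 false calls among 49760 genes. Only 100 genes were changed at each size, and the waterlogged groups otherwise had the profile of their controls, so the TMM assumption of few changes held. The changed genes averaged at least 20 counts over the libraries, so the recovered shares do not cover low-count genes. Every group was drawn with the same spread per gene, so the false calls do not cover groups of unequal spread. In the real comparisons most genes were called, so these rates need not apply to them. The 24 pairs of replicate libraries differed beyond sampling noise, with chi-square values of 2.79 to 6.06 per degree of freedom over genes with at least 20 counts, and none were treated as duplicates.

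Alternatives chosen before the data were examined were RLE and upper-quartile scaling, no low-count filter, a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1), the replicate number as a block, only the libraries of the groups compared, a 2-fold threshold, and leaving out each library in turn. Thinning every library to 21000000 counts, removing a gene-length trend, leaving out the 100 most abundant genes and scaling by library totals alone, and axes averaged over both varieties, were added after seeing the data.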

Results

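The study asked how roots of 2 cotton varieties respond to waterlogging and to the recovery that follows it. Variety 9001 is described by the submitters as tolerant of waterlogging and variety 4847 as sensitive to it. Seedlings were kept for 96 h in darkness, either drained (control) or waterlogged. Roots were taken at the end of that period (0 h) or after a further 24 h in the light, with the waterlogged plants drained (24 h). Each of the 8 groups had 3 libraries. Waterlogged 4847 at 24 h had 22035053 ± 539319 counts (SD, n = 3), against 36512178 to 39388041 as the means of the other 7 groups. The variation between replicate libraries beyond sampling noise, as a biological coefficient of variation, was 5.78% to 7.23% in the control groups. It was 10.5% and 11.4% in waterlogged 4847 and 9001 at 0 h, and 14.4% and 6.59% in those groups at 24 h. Since the fit shares the spread over groups, p-values of comparisons with waterlogged 4847 at 24 h may be too small.

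At equal depth, fewer genes were detected in waterlogged roots than in their controls at both times, and at 24 h the deficit was larger in 4847. With every library thinned to 21000000 counts, 35414 ± 169.9 genes had at least 10 counts in waterlogged 9001 at 0 h, against 39623 ± 77.2 in its control (SD, n = 3 each). In 4847 the numbers at 0 h were 36005 ± 88.3 and 39039 ± 56.0. After 24 h the controls had risen to 45169 ± 65.8 genes in 9001 and 45059.7 ± 95.4 in 4847. Waterlogged 9001 then had 43602 ± 89.2 and waterlogged 4847 had 38990.3 ± 67.7, near its control at 0 h. The counts were also concentrated in fewer genes after waterlogging. That by itself can lower the number detected at a fixed depth, so fewer detected genes need not mean fewer expressed genes. The 100 most abundant genes of a library held 19.6% ± 0.255 of counts in waterlogged 9001 and 17.8% ± 0.201 in waterlogged 4847 at 0 h, against 13.4% ± 0.201 and 13.1% ± 0.0532 in the controls. At 24 h they held 11.3% ± 0.0683 in waterlogged 9001 and 14.9% ± 0.154 in waterlogged 4847, against 9.71% ± 0.0394 and 10.1% ± 0.0588 in the controls. The libraries of the groups did not overlap in any of these comparisons, and each had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 allows.

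**Figure D1:**
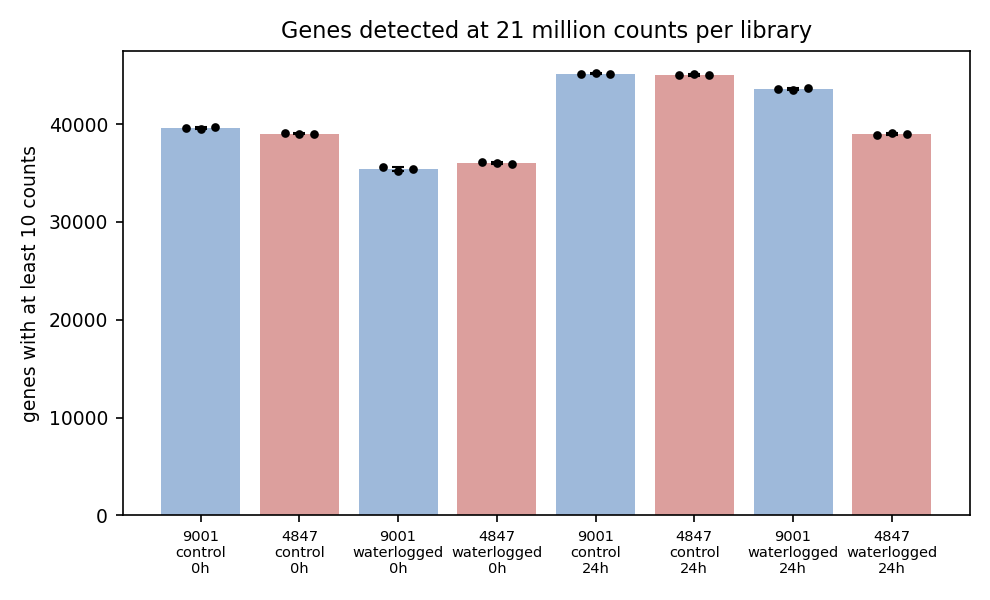
Genes with at least 10 counts per library after thinning each library to 21000000 counts, with bars as means, error bars as the SD of 3 libraries, and points as libraries. Waterlogged 4847 rose from 36005 genes at 0 h to 38990.3 at 24 h, when its control stood at 45059.7.

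Waterlogging at 0 h, the response to flooding itself, changed the expression of most genes in both varieties. In 9001, 13065 genes rose and 15076 fell at least 2-fold, and in 4847, 12675 rose and 13757 fell (edgeR, adjusted p under 0.05). Ghir_A08G017190 had no counts in the 9001 control and 1102 ± 24.3 CPM in waterlogged 9001 roots (SD, n = 3), at least 44495-fold higher. In 4847 it had no counts in the control and 650.05 ± 21.5 CPM under waterlogging, at least 26130-fold higher. Ghir_A09G017520 reached 3700 ± 185 CPM in waterlogged 9001, where the 3 control libraries together held 1 count, and 2732 ± 140.1 CPM in waterlogged 4847, where the control libraries also held 1 count. Among the genes that fell, Ghir_A08G018050 went from 57.1 ± 2.35 CPM to no counts in 9001, at least 1233-fold lower. In 4847 the same gene went from 28.6 ± 1.89 CPM to 1 count in 3 libraries, a ratio of 2049.5 (exact 95% interval 368 to 80975). Ghir_D08G018960 went from 31.9 ± 4.39 CPM to no counts in 9001, at least 688-fold lower, and from 17.8 ± 1.27 CPM to 1 count in 4847, a ratio of 1276 (229 to 50425). The files give no name or function for these IDs. A and D chromosome genes were called at similar rates. In 9001, 26.0% of tested A genes and 25.6% of tested D genes rose at least 2-fold, and 29.7% and 29.9% fell.

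The same genes carried most of the response in both varieties at 0 h. Of the 2-fold risers, 10949 rose in both, which is 83.8% of those in 9001 and 86.4% of those in 4847, where independent lists would share 3270. Of the 2-fold fallers, 11995 fell in both, against 4096 for independent lists. Opposite 2-fold changes were found for 26 genes that rose in 9001 and 38 that fell in it. The groups compared share no libraries. Across the tested genes, which are not independent replicates, the log2 fold changes of the varieties correlated at 0.889.

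Without the 2-fold condition, 38927 genes passed the test in 9001 (18301 higher, 20626 lower) and 37944 in 4847 (18433 higher, 19511 lower). The balance of higher and lower calls depended on the scaling: with library totals as the only scaling, 11375 were higher and 29676 lower in 9001, and 12122 higher and 27272 lower in 4847. With RLE scaling the higher genes were the more numerous in both, at 19387 against 19345 and 19258 against 18578, and at 2-fold limma on log2(FPKM + 1) called 18610 genes in 9001 and 16187 in 4847.

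**Figure D2:**
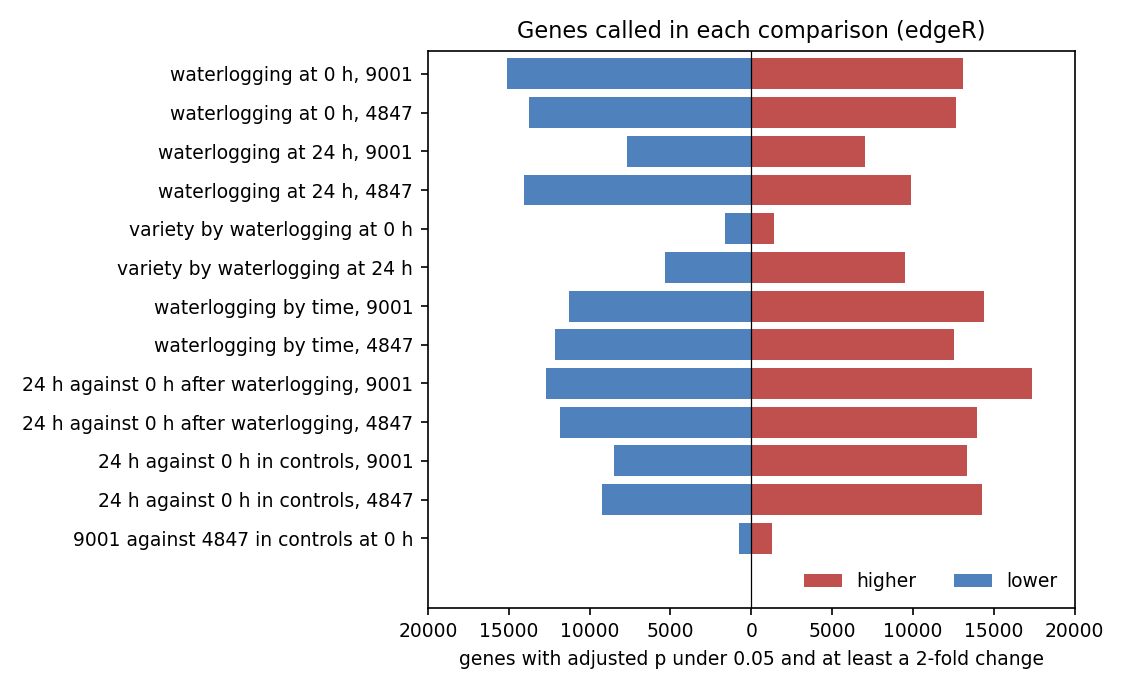
Genes with adjusted p under 0.05 and at least a 2-fold change in each of the 13 comparisons (edgeR, TMM scaling), with lower genes drawn to the left and higher genes to the right. Waterlogging called 28141 genes in 9001 and 26432 in 4847 at 0 h, and 14683 and 23917 at 24 h.

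The difference between the varieties in their response at 0 h was tested directly. The response differed at least 2-fold for 3021 genes, of which 1409 had the higher response (log2 fold change) in 9001 and 1612 in 4847. Ghir_A08G017190, Ghir_A08G018050 and Ghir_D08G018960 were not called, and neither was Ghir_A09G017520 (edgeR adjusted p = 0.947), but with 0 or 1 count in a whole group this test has little to work with for any of them. In all, 9841 genes passed, 5052 with the higher response in 9001 and 4789 in 4847. With library totals as the only scaling the split was 3136 and 9491, and at 2-fold limma on log2(FPKM + 1) called 732 genes.

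After 24 h of recovery the waterlogging response had shrunk in 9001 and stayed broad in 4847. In 9001, 7026 genes were at least 2-fold higher and 7657 lower than in controls of the same time. In 4847, 9846 were higher and 14071 lower. Ghir_A08G017190 had dropped to 62.3 ± 1.26 CPM in 9001 and 21.3 ± 0.970 CPM in 4847 (SD, n = 3). Its control had no counts in 9001, so it was still at least 3612-fold higher there, and 1 count in 4847, a ratio of 3665 (exact 95% interval 657 to 144884). Ghir_A09G017520 had dropped to 50.5 ± 1.68 CPM in 9001 and 59.3 ± 2.33 CPM in 4847, ratios to control of 585 (355 to 1047) and 2555 (997 to 9383). Ghir_A08G018050 was 2.28 ± 0.228 CPM in waterlogged 9001 and 1.01 ± 0.120 CPM in its control, a log2 fold change of 1.17 (SE 0.161, edgeR adjusted p = 3.39e-08). In 4847 it was at 0.586 ± 0.268 and 0.587 ± 0.0921 CPM, with no difference by edgeR (log2 fold change 0.01, adjusted p = 0.985). That value turned to a fall of the log2 fold change to -0.70 with library totals as the only scaling. Ghir_D08G018960 was higher in both varieties, by a log2 fold change of 1.74 in 9001 (SE 0.163, edgeR adjusted p = 1.74e-12) and 0.82 in 4847 (SE 0.237, edgeR adjusted p = 0.00218). The call in 4847 was lost with library totals as the only scaling, where the log2 fold change was 0.11. It was also lost with the FPKM settings and with only the libraries of the groups compared.

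The overlap between varieties at 24 h was uneven. The 5349 genes higher in both made up 76.1% of those higher in 9001 and 54.3% of those higher in 4847, with 1366 expected of independent lists. The 6146 genes lower in both made up 80.3% of those lower in 9001 and 43.7% of those lower in 4847, with 2128 expected. The log2 fold changes correlated at 0.755 across genes. Of the genes called at 24 h, 34.4% in 9001 and 41.2% in 4847 had no 2-fold call at 0 h in the same variety. These were 2243 higher and 2802 lower genes in 9001, and 3897 higher and 5945 lower genes in 4847.

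At 24 h without the 2-fold condition, 30304 genes passed in 9001 (16083 higher, 14221 lower) and 37640 in 4847 (17985 higher, 19655 lower). In 4847 the split was 14113 and 24216 with upper-quartile scaling. With library totals alone it was 9692 and 31678 in 4847 and 11338 and 21012 in 9001. In 9001 the lower genes were also the more numerous with RLE (14519 higher, 15833 lower) and upper-quartile scaling (13665 and 17040), and at 2-fold limma on log2(FPKM + 1) called 8396 genes.

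Among the genes that had risen or fallen together in both varieties at 0 h, the fallers lay closer to their 24 h control in 9001 than in 4847. For the risers the order depended on the scaling. The controls also changed between 0 h and 24 h, so a gap could close because the control moved, without recovery of the waterlogged roots. Of the 11995 shared fallers, 26.0% were still at least 2-fold lower at 24 h in 9001 and 43.3% in 4847. Their median log2 fold change went from -2.41 to -0.38 in 9001 and from -2.21 to -0.80 in 4847, and 4847 kept the lower median under each of the 5 other scalings and FPKM settings tried. The sizes at 24 h moved with the scaling, to -0.65 in 9001 and -1.51 in 4847 with library totals alone and to -0.61 and -1.42 with log2(FPKM + 0.1). Of the 10949 shared risers, 30.4% were still at least 2-fold higher in 9001 and 39.6% in 4847. Their median went from 2.66 to 0.48 in 9001 and from 2.46 to 0.71 in 4847, but with library totals as the only scaling the medians at 24 h were 0.22 and 0.00, which turns that order. The medians of the risers at 0 h were smaller with the FPKM settings, at 1.41 and 1.35 with log2(FPKM + 0.1) and 0.82 and 0.80 with log2(FPKM + 1). With genes at 0 counts in a whole group set at their bound, these medians at 24 h were -0.38 and -0.79 for the fallers and 0.47 and 0.69 for the risers, and at 0 h -2.37 and -2.17 for the fallers and 2.63 and 2.42 for the risers, in 9001 and 4847. Some of these genes had crossed to the other side. Of the shared risers, 7.28% in 9001 and 15.4% in 4847 were at least 2-fold below control at 24 h, and of the shared fallers, 6.30% and 8.84% were at least 2-fold above it.

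The change in the waterlogging response from 0 h to 24 h, to which the change of the controls also contributes, was tested within each variety. In 9001 it differed at least 2-fold for 25653 genes, 14391 with the higher value at 24 h and 11262 with the lower. In 4847 it differed for 24705 genes, 12542 higher and 12163 lower. Ghir_A08G018050 and Ghir_D08G018960, which had nearly vanished at 0 h, had the higher value at 24 h in both varieties, with adjusted p of 4.14e-30 and 1.74e-28 in 9001 and 4.82e-18 and 1.50e-21 in 4847 (edgeR). For Ghir_A08G018050 in 9001, the control fell from 57.1 to 1.01 CPM, while waterlogged roots went from no counts to 2.28 CPM. Ghir_A09G017520 had the lower value at 24 h, with adjusted p of 5.12e-15 in 9001 and 4.27e-06 in 4847 (edgeR). Ghir_A08G017190 also had the lower value at 24 h in 4847 (edgeR adjusted p = 0.0206) and was not called in 9001 (edgeR adjusted p = 1.00), where neither control group had a count. In all, 34540 genes passed in 9001 (19189 higher, 15351 lower) and 33640 in 4847 (17662 higher, 15978 lower). With library totals alone the split in 9001 was 25678 and 10595, and with DESeq2 it was 17614 and 17965. In 4847 the lower genes became the more numerous with RLE (15839 higher, 17716 lower), upper-quartile scaling (15792 and 17787), DESeq2 (16359 and 19169) and limma on log2(FPKM + 1) (16004 and 22247).

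The varieties differed more in their waterlogging response at 24 h than at 0 h. The response was at least 2-fold higher in 9001 for 9496 genes and lower in 9001 for 5353. These groups were chosen by that difference in the same libraries, so a gap between their medians follows from the choice. The choice does not fix which variety changed more. In the first group the median log2 fold change was -0.22 in 9001 and -2.41 in 4847, and 5262 of its genes were lower in 4847 with no 2-fold change in 9001. In the second group the medians were 0.25 in 9001 and 1.83 in 4847, and 2218 of its genes were higher in 4847 with no 2-fold change in 9001. With library totals as the only scaling the medians were -0.49 in 9001 and -3.12 in 4847 for the first group and -0.01 and 1.12 for the second. With limma on log2(FPKM + 1) those in 4847 were -1.31 and 0.79. With genes at 0 counts set at their bound the medians in 4847 were -2.35 and 1.83. The change was larger in size in 4847 for 87.8% of the first group and 79.5% of the second. Opposite 2-fold changes were found for 184 genes of the first group and 125 of the second. Ghir_A08G018050 and Ghir_D08G018960 had the higher response in 9001, by 1.16 (SE 0.330, edgeR adjusted p = 0.00290) and 0.92 (SE 0.285, edgeR adjusted p = 0.00591) on the log2 scale. Ghir_A09G017520 had the lower response in 9001 (edgeR adjusted p = 0.00811), over controls with 15 counts in 9001 and 4 in 4847, and Ghir_A08G017190 was not called (edgeR adjusted p = 0.152). A total of 27245 genes passed, 14596 with the higher response in 9001 and 12649 with the lower, and with library totals alone the split was 23281 and 6936. At 2-fold, limma on log2(FPKM + 1) called 8708 genes.

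**Figure D3:**
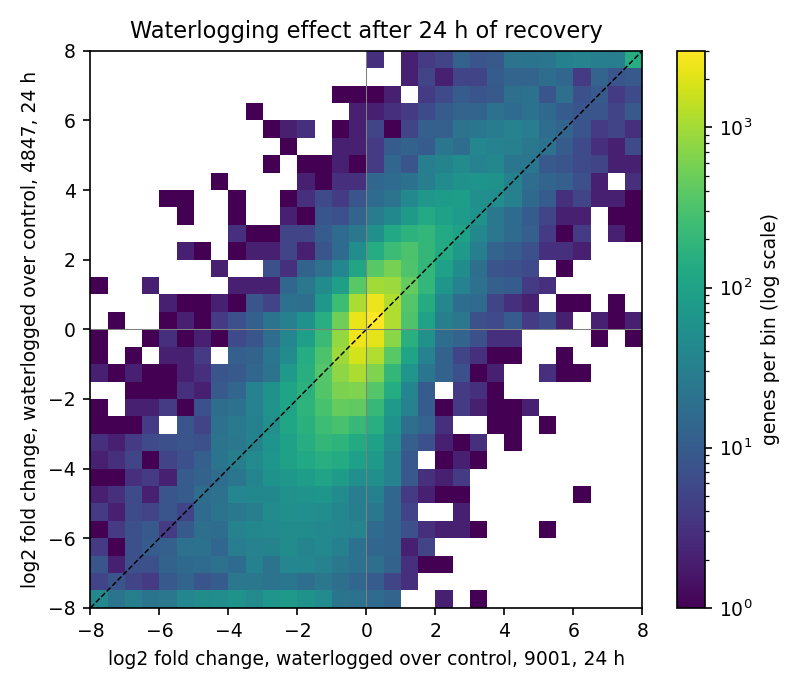
Number of genes (colour, log scale) by log2 fold change of waterlogged over control roots at 24 h in 9001 (x axis) and 4847 (y axis), in bins of log2 0.5, with values beyond the axes drawn in the edge bins. The dashed line marks equal change, and the cloud is steeper than it, with 87.8% of the 9496 genes of higher response in 9001 changed more in 4847.

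The control plants themselves changed widely between 0 h and 24 h, when they passed from darkness to light, and without a control kept dark the light and the elapsed time are not separated. In 9001, 13355 genes rose and 8518 fell at least 2-fold, and in 4847, 14286 rose and 9201 fell. Both varieties shared 11998 risers and 7387 fallers, and their log2 fold changes correlated at 0.923 across genes. Ghir_A08G018050 and Ghir_D08G018960 were among the fallers of both varieties, with log2 fold changes of -5.81 and -4.64 in 9001 and -5.60 and -4.37 in 4847. Ghir_A09G017520 was called higher at 24 h in 9001 (edgeR adjusted p = 0.00236), on 15 counts against 1, and not in 4847 (edgeR adjusted p = 0.357), and Ghir_A08G017190 was called in neither. At adjusted p under 0.05 alone, 37191 genes were called in 9001 (19478 higher, 17713 lower) and 38362 in 4847 (20199 higher, 18163 lower). With library totals alone these splits were 27407 and 11051 in 9001 and 27499 and 11676 in 4847. At 2-fold, limma on log2(FPKM + 1) called 12572 genes in 9001 and 13870 in 4847.

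The genes that rose from 0 h to 24 h in controls were lower in formerly waterlogged roots, and more so in 4847. In 9001, the 14286 genes that rose in the other variety's controls had a median log2 fold change between waterlogged and control roots of -0.47 at 24 h, and 33.6% were at least 2-fold lower. In 4847, the 13355 genes chosen in the same way had a median of -1.88, and 63.1% were at least 2-fold lower. From 0 h to 24 h these genes rose by a median log2 of 2.16 in control and 1.89 in waterlogged roots of 9001, and by 2.60 and 0.64 in those of 4847. With genes at 0 counts set at their bound these values were 2.13 and 1.67 in 9001 and 2.54 and 0.50 in 4847, and the medians at 24 h were -0.47 and -1.83. The rises themselves were not taken under other scalings. With library totals alone the median change of all tested genes shifted by 0.48 in control and 1.06 in waterlogged 9001, and by 0.49 and 0.45 in 4847. The order of the 2 rises in 9001 may therefore turn with the scaling. Genes that fell from 0 h to 24 h in the other variety's controls were higher in formerly waterlogged roots, by a median log2 of 0.43 over 9201 genes in 9001 and 0.87 over 8518 genes in 4847. With library totals as the only scaling both of those medians were 0.16, so the difference between varieties was seen only with added scaling factors, whereas for the control risers the median stayed lower in 4847 under every scaling tried, at -0.74 and -2.59 with totals alone.

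On the control axis, which runs from the control at 0 h at 0 to the 24 h control of the other variety at 1, waterlogged 9001 roots at 24 h stood at 0.522 ± 0.00311 and waterlogged 4847 roots at 0.241 ± 0.00111 (SD, n = 3). Their own controls at 24 h stood at 0.874 ± 0.00246 and 1.04 ± 0.00218, so the waterlogged roots had reached 59.7% of the control value in 9001 and 23.2% in 4847. On the waterlogging axis they stood at 0.298 ± 0.00132 in 9001 and 0.371 ± 0.00206 in 4847, down from 1.03 ± 0.00119 and 0.863 ± 0.00211 at 0 h. These axes differ between the varieties. On axes averaged over both varieties, waterlogged roots at 24 h stood at 0.577 ± 0.00317 in 9001 and 0.230 ± 0.00116 in 4847 on the control axis, where the controls at 24 h stood at 0.956 and 1.04. For waterlogging they stood at 0.304 ± 0.000929 and 0.403 ± 0.00239. On these common axes the libraries of the varieties did not overlap, with an exact two-sided permutation p of 0.1 each, the smallest possible.

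**Figure D4:**
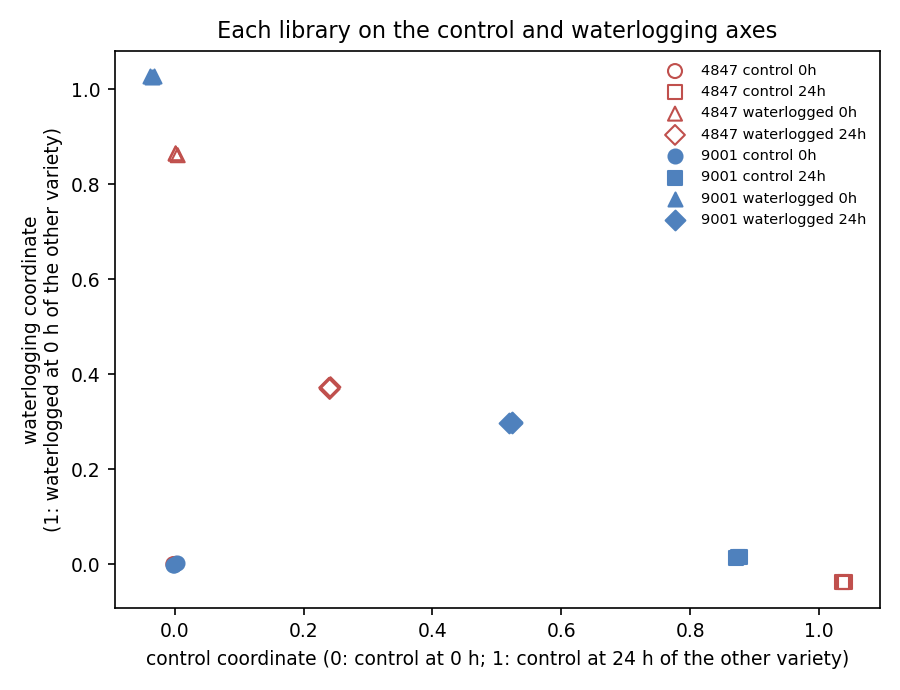
Position of each library on the control axis (x) and the waterlogging axis (y), both defined in the other variety and without unit. Waterlogged roots at 24 h stood at 0.522 in 9001 and 0.241 in 4847 on the control axis.

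From 0 h to 24 h, waterlogged roots changed at least 2-fold in 30070 genes in 9001, 17381 higher and 12689 lower, and in 25749 genes in 4847, 13936 higher and 11813 lower. Ghir_A08G017190 fell by 4.14 on the log2 scale in 9001 and fell by 4.93 in 4847, and Ghir_A09G017520 fell by 6.19 and fell by 5.52. Ghir_A08G018050 and Ghir_D08G018960 rose, with adjusted p of 7.17e-17 and 1.98e-19 in 9001 and 1.04e-07 and 2.20e-12 in 4847 (edgeR). In root-mean-square log2 distance over the tested genes, waterlogged 9001 at 24 h lay nearer its control at 24 h (1.44) than its control at 0 h (1.71). Waterlogged 4847 at 24 h lay nearer its control at 0 h (1.63) than its control at 24 h (2.10). At adjusted p under 0.05 alone, 40239 genes were called in 9001 (22108 higher, 18131 lower) and 36733 in 4847 (19406 higher, 17327 lower). With library totals alone these splits were 33098 and 9577 in 9001 and 24476 and 12892 in 4847. In 4847 limma on log2(FPKM + 1) called 14180 genes at 2-fold. With only the libraries of the groups compared, 31310 genes passed in 4847 without the 2-fold condition.

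The varieties were much closer to each other in control roots, at both times, than in waterlogged roots at 24 h. At 0 h, 1292 genes were at least 2-fold higher and 743 lower in 9001 than in 4847, and 7498 passed the test in all (3783 higher, 3715 lower). At 2-fold, limma on log2(FPKM + 1) called 463 genes. Ghir_A08G018050 and Ghir_D08G018960 were higher in 9001 by 1.00 (SE 0.0954) and 0.84 (SE 0.122) on the log2 scale, both called by edgeR, whereas Ghir_A08G017190 and Ghir_A09G017520 had at most 1 count in each of these groups and were not called. The distance between the varieties was 0.576 in controls at 0 h, 0.568 in controls at 24 h, 0.742 in waterlogged roots at 0 h and 1.28 in waterlogged roots at 24 h.

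TMM scaling assumes that most genes do not change, whereas most tested genes were called in all comparisons but those of the variety in controls and of the variety difference in response at 0 h, so fold changes are relative to the scaling used. Against TMM, the median log2 fold change of all tested genes shifted with library totals alone by -0.86 and -0.67 for waterlogging at 0 h in 9001 and 4847, and by -0.27 and -0.71 at 24 h. For the change from 0 h to 24 h it shifted by 0.48 and 0.49 in controls and by 1.06 and 0.45 in waterlogged roots.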

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

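The tests of depth and gene length below, leaving out the 100 most abundant genes, scaling by library totals alone, and the use of upper-quartile scaling (itself planned) as a test of abundant genes were chosen after the results were seen. Differences between groups under the same contrast, each tested as an interaction, put 4 results here. The response to waterlogging differed between varieties for 9841 genes at 0 h and 27245 at 24 h, and it differed between 0 h and 24 h for 34540 genes in 9001 and 33640 in 4847 (edgeR, adjusted p under 0.05).

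Exchanging labels within each treatment was tried for these 4 results, with 25 splits each including the real one. The real split called the most genes in each case, 1 of 25. The highest of the others called 7232, 23535, 29569 and 20453 genes, in the order above. Those high splits kept the real labels within 1 treatment. Among splits that broke the labels in both treatments the highest counts were 5, 0, 0 and 1. Such splits put libraries of unlike groups under the same label, which by itself raises the spread and lowers the count. The libraries of a group may also be technical replicates. The splits therefore cannot decide whether chance assignment or chance differences between plants gave these results, and no conclusion is drawn from them.

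Waterlogging at 24 h changed 23917 genes at least 2-fold in 4847 and 14683 in 9001, a ratio of 1.63. The waterlogged 4847 libraries at 24 h had lower depth, but with every library thinned to the same depth, which removes that difference, the ratio was 1.65. With the gene-length trend of each library removed it was 1.63, which argues against a length trend as the whole cause. With upper-quartile factors, which do not read the most abundant genes, it was 1.66. The TMM scaling behind the ratio of 1.63 already trims the most abundant genes, so the upper-quartile value cannot decide whether a few of them set the scale. Leaving out the 100 most abundant genes (1.63) moved little else and decides nothing, and with library totals as the only scaling the ratio was 1.79. A different makeup of the roots, RNA damage or a handling difference of that group stays open, as does a difference between the varieties themselves, which the design names and which was not tested apart from these.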

How the results depend on the processing

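Thinning to 21000000 counts, removing the gene-length trend, leaving out the 100 most abundant genes, scaling by library totals alone and averaging the axes over both varieties were chosen after the data were seen. Without a 2-fold condition, each count of called genes stayed within 1.5 times its value under every setting tried, with waterlogging at 24 h ranging from 28133 to 34462 genes in 9001 and from 35027 to 42048 in 4847. With the 2-fold condition this held for every setting but limma on log2(FPKM + 1), whose offset shrinks the folds of genes with low FPKM. There the 2-fold counts were 18610 and 16187 for waterlogging at 0 h in 9001 and 4847, 8396 at 24 h in 9001, 732 and 8708 for the variety difference in response at 0 h and 24 h, 14180 for time after waterlogging in 4847, 12572 and 13870 for time in 9001 and 4847 controls, and 463 between varieties. The scaling sets which side of 0 a gene with a modest change falls on. The settings that use library totals alone, FPKM included, lack the TMM factors by construction, and those averaged 0.897 in waterlogged 4847 at 24 h against 1.47 in its control. Depth limits genes with few counts: with 0 or 1 count in a whole group, none of the 4 named genes could be placed in the variety difference at 0 h, where the smallest SE was 1.71 on the log2 scale. The set tests camera and fry and their alternatives were not run, since the files give no gene names. DESeq2 gave no adjusted p for 984 genes in the variety comparison of the response at 0 h. Where nothing else is said, the cause of a shift was not tested.

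Requiring 2-fold left 14683 (9001) and 23917 (4847) genes for waterlogging at 24 h, 3021 and 14849 for the variety difference in response at 0 h and 24 h, 21873 and 23487 for time in 9001 and 4847 controls, and 2035 between varieties, fewer by construction. For Ghir_A08G018050 in 4847 at 24 h the log2 fold change of 0.01 turned to -0.70 with library totals alone, -0.68 with log2(FPKM + 0.1) and -0.29 with log2(FPKM + 1). For Ghir_D08G018960 in 4847 at 24 h the call was lost at 0.11, 0.13 and 0.07 in the same order, and at 0.77 with only the libraries compared (adjusted p = 0.0581, edgeR). The other 201 values of the named genes under these settings kept their side of the threshold. Among them the uncalled value of Ghir_A08G018050 in 4847 at 24 h turned slightly negative under 6 settings, the lowest being -0.27 with upper-quartile factors.

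The ratio of 2-fold calls at 24 h (4847 over 9001) moved from 1.63 to 1.79 with library totals alone, 1.85 with log2(FPKM + 0.1) and 1.95 with log2(FPKM + 1). The percent of genes changed at 0 h in both varieties and still changed at 24 h moved in 9001 from 28.1 to 26.7 and 21.2 with the FPKM settings. In 4847 it moved from 41.5 to 50.8 with library totals alone, 49.4 and 38.04 with the FPKM settings, 43.3 with upper-quartile factors, 42.6 with the 1 CPM filter and 40.6 with no filter. The correlation at 0 h moved from 0.889 to 0.954 and 0.966 with the FPKM settings, 0.914 with the 1 CPM filter, 0.905 with DESeq2 and 0.832 with no filter. At 24 h it moved from 0.755 to 0.792 and 0.811 with the FPKM settings, 0.786 with the 1 CPM filter and 0.693 with no filter.

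For genes higher at 24 h than at 0 h in controls of the other variety, selected anew under each setting, the median log2 difference at 24 h in 9001 moved from -0.47 to -0.60 with library totals alone, -0.56 with log2(FPKM + 0.1), -0.53 with upper-quartile factors, -0.50 with RLE, -0.52 with the length trend removed, -0.49 with DESeq2, -0.42 with the 1 CPM filter and -0.50 with no filter. In 4847 it moved from -1.88 to -2.11 with library totals alone, -1.82 and -1.37 with the FPKM settings, -1.95 with upper-quartile factors, -1.82 with RLE, -1.82 with the length trend removed, -1.81 with DESeq2, -1.81 thinned, -1.76 with the 1 CPM filter and -1.95 with no filter. The coordinate on the control axis in 9001 moved from 0.522 to 0.577 with averaged axes, 0.542 with library totals alone, 0.530 with the 1 CPM filter and 0.517 with no filter. In 4847 it moved from 0.241 to 0.230 with averaged axes, 0.225 with library totals alone, 0.228 with upper-quartile factors, 0.237 with RLE, 0.249 thinned, 0.251 with the 1 CPM filter and 0.237 with no filter.

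Leaving out each library in turn gave correlations of 0.871 to 0.881 at 0 h and 0.731 to 0.750 at 24 h, a ratio of 1.59 to 1.68, medians of the control risers of -0.49 to -0.47 in 9001 and -1.94 to -1.89 in 4847, and coordinates on the control axis of 0.516 to 0.522 and 0.235 to 0.241. The correlations with all libraries, 0.889 and 0.755, lay above these ranges, and the medians of the control risers lay just outside theirs. The low-count filter was applied anew each time, so the tested genes could change, and its part in these shifts was not tested. The numbers of the replicates do not pair the libraries: after removing group means, libraries of the same number correlated at a mean of -0.00218 over 84 pairs of libraries, and 6 of 24 libraries were closest to one of their own number. With the replicate number as a block, the counts were 38667 and 37682 for waterlogging at 0 h in 9001 and 4847, 29739 and 37334 at 24 h, 9479 and 26728 for the variety difference at 0 h and 24 h, 34204 and 33334 for waterlogging by time, 39979 and 36452 for time after waterlogging, 36797 and 38038 for time in controls, and 7160 between varieties.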

Other observations

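The tests of random placement, shuffling of neighbours and counts of nearly absent genes in this part were chosen after the data were seen. Genes that responded to waterlogging had neighbours that responded alike. Of the genes changed at least 2-fold at 0 h in 9001, 9464 pairs of adjacent tested genes moved in the same direction, against a mean of 7856 and a highest of 8044 in 100 shuffles within chromosomes. At 24 h there were 3065 pairs in 9001 against a mean of 2137, and 7197 in 4847 against 5830. Chromosomes differed little. The share of tested genes changed at least 2-fold at 0 h in 9001 ran from 53.6% to 57.9% over the 26 chromosomes. The D chromosomes held 51.0% ± 0.00617 of counts in 4847 controls at 24 h and 52.3% ± 0.0638 in waterlogged 4847, and 51.2% ± 0.0181 and 51.8% ± 0.0356 in the same groups of 9001 (SD, n = 3, exact permutation p = 0.1 each, the smallest possible). The mean length of the genes that were counted, weighted by counts, was 2362 ± 3.22 bases in waterlogged 4847 and 2393 ± 5.20 in waterlogged 9001 at 24 h, below the controls of that time at 2515 ± 5.85 and 2540.0 ± 8.66.

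Some genes had counts in one variety and almost none in the other. Over the 12 libraries of each variety, 36 genes had at most 12 counts in total in 4847 while averaging at least 1 CPM in 9001, and 27 had the opposite pattern. Of these 63 genes, 14 lay in the clusters described next.

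The genes that differ at least 2-fold between varieties in controls at 0 h lay in clusters of neighbouring IDs, with 7 clusters (windows of 25 genes holding at least 8 such genes, merged) on chromosomes A06, A10, D02, D05, D06 and D11. Random placement is argued against, since 1000 shuffles gave a mean of 0.039 such clusters and at most 2, and 0 of them had a window as full as the 13 genes seen on D11, where the shuffles reached 10. A stretch in which reads of only a single variety fail to match the reference would lower its genes together. In the median cluster 62.5% of the called genes went the same way, which argues against that as the whole explanation. Where both varieties differ from the reference, each could lose reads at different genes, and mixed directions would follow. The build is not known, so failed matching in both varieties stays open. Of the 63 nearly absent genes, 14 lay in these clusters, which hold 230 of the 50638 tested genes and 69 of the 2035 called genes. A nearly absent gene can itself be a called gene that helps to define a cluster, so no conclusion is drawn from this share. Of the called genes in the clusters, 40.6% kept their direction at 2-fold or more in all 3 other conditions, and outside the clusters 12.8% did. The value lay under the 50% bound set beforehand for a passing difference in the state of the control plants. Those conditions include waterlogged roots, where the response itself differed between varieties, so a lasting difference could also fall under the bound. The value therefore cannot decide, and a passing difference stays open. A difference between the varieties in these regions stays open and was not tested.

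Other splits of the libraries were counted for the 9 comparisons of 2 groups, which have 10 splits each, the real one included, so that 1 of 10 is the lowest share they allow, too few for a share under 0.05. For waterlogging the real splits called 38927 genes in 9001 and 37944 in 4847 at 0 h, and 30304 and 37640 at 24 h, with 0 as the highest of the other splits. For 24 h against 0 h in controls they called 37191 and 38362, again with 0 as the highest other. In waterlogged roots they called 40239 in 9001, highest other 0, and 36733 in 4847, highest other 11. Between varieties in controls at 0 h they called 7498, highest other 2.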
